A study of Arabidopsis thaliana with 20 samples.

How the data were processed

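The values were log2 expression values made with RMA (robust multi-array average, in the affy package), which the authors deposited for each probe set and array. The submitters' notes gave no version of either. No further transformation or normalization was applied, because array medians already lay between 6.141 and 6.41. Of the 22810 probe sets, 64 control probe sets were left out, and 22746 were tested. The controls included those for ribosomal RNA, actin and GAPDH that are used below. Gene names came from a probe table that listed 14016 probe sets. Of these, 13513 named 1 gene and 503 named several, and 8730 of the tested probe sets had no name in it. Locus tags of the TAIR10.1 RefSeq annotation matched 13436 of the 1-gene probe sets and left 77 unmatched. Genome positions are not given, because the labels name no genome build.

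Each probe set was fitted with limma (version 3.58.1 in R 4.3.3; lmFit, then eBayes) on the means of 10 groups of 2 arrays. The residual spread was shared over all 20 arrays, with 10 residual degrees of freedom and 7.04 prior degrees of freedom. A probe set was called when its two-sided p, adjusted by Benjamini and Hochberg within a comparison, lay under 0.05. No minimum change was asked for, and counts that also ask for a 2-fold change are given with the other alternatives. Submerged tissue was compared with darkened tissue of the same duration, and darkened tissue with tissue harvested in the light at 0 h. Differences between tissues and between times were tested as contrasts of contrasts in the same fit.

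Gene lists came from published knowledge of flooding, sugar starvation and light, and were fixed by locus with the contrasts, the test, the threshold and the planned other settings before the data were examined. There were 27 lists holding 549 genes, of which only 105 genes had a 1-gene probe set. Lists with at least 3 measured genes were tested, a limit set after the probe table was read and before any list test. That left 14 lists, and 13 were too small. Counts of list genes below cover measured genes only. These were 9 of 9 listed for ATG8, 21 of 45 for core low-oxygen and 5 of 11 for shoot markers. Wall loosening had 9 of 24, starch 5 of 17, nucleolar genes 3 of 10 and glycolysis 10 of 39. Sugar starvation and heat shock each had 6 of 26, photosynthesis 9 of 46 and ribosomal proteins 4 of 22. Anthocyanin had 3 of 20, immunity 3 of 21 and oxidative stress 3 of 24. Among the small lists, those for group VII ethylene response factors, jasmonate, aquaporins and nitrate had no measured gene at all. Most of the best known low-oxygen genes, alcohol dehydrogenase among them, were not named in the probe table, so the core low-oxygen list rested on its remaining 21 genes.

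Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, against all other genes and adjusted over the lists of a comparison. A single probe set stood for a gene, the brightest of its 1-gene probe sets, over 13355 genes. Each list test was repeated with a correlation estimated from the residuals. It was also repeated with fry, which asks whether a list's genes move one way on balance and compares them with no other genes. Of 53 list calls, 44 were lost with an estimated correlation and 14 with fry. The 9 calls that held with an estimated correlation were the core low-oxygen list in submerged roots at both times, sugar starvation and wall loosening in dark roots at 7 h, wall loosening in dark roots at 24 h, and sugar starvation and anthocyanin in dark shoots at both times.

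Genes were named by a rule in 6 parts. The first part took, in each submergence comparison, the 10 largest rises and 10 largest falls among called 1-gene probe sets whose submerged arrays lay on 1 side of both dark arrays. The next took 6 and 6 in each darkness comparison, the third 5 and 5 in each tissue or time difference, and the fourth 3 and 3 between the tissues in light. The fifth took 12 well known low-oxygen genes whatever their values, of which only HRA1 had a 1-gene probe set. The last took up to 4 called members with the largest changes from each list in each comparison. Genes outside the rule are said to be chosen after their values were seen.

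The alternatives were a filter that kept the 15129 probe sets above a log2 value of 6 on at least 2 arrays, 1-gene probe sets only, quantile normalization again, median centring, only the arrays of 1 tissue, a variance trend with intensity and robust estimation, a 2-fold minimum, the replicate number as a block, and leaving out each array in turn. Fits without the light arrays, tests of 45 families of gene symbols or plastid-encoded genes, and leave-one-out overlaps were added after the data were seen. In leave-one-out fits the lone remaining array of a group was taken to vary like the other groups.

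The procedure was run on simulated arrays in which 200 of 22746 probe sets were changed. For submerged against dark roots at 7 h it called 16 of 67 changes of log2 0.5, 60 of 67 changes of 1 and 66 of 66 changes of 2, with 3 false calls. Changes of log2 0.5 were thus mostly missed in this simulation, with 2 arrays per group and 200 probe sets changed. The real comparisons called between 330 and 13449 probe sets, so the share missed here does not carry over to them. False calls reached 11 in another simulated comparison, submerged against dark shoots at 24 h. The list test called the changed list and 0 of 100 unchanged lists. The simulated noise was independent between probe sets, so this does not cover lists whose genes vary together. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.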

Results

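Transcript levels were measured on Affymetrix ATH1 arrays in roots and rosette leaves of Arabidopsis thaliana, accession Col-0, at a rosette of 9 to 10 leaves. The rosette samples are called shoots here. Plants were put under water in the dark, or kept in air in the same dark chamber, for 7 or 24 h. A further set was harvested in the light at 0 h. Submergence began 2 h into a light period of 9 h at 20 °C. Each of the 10 groups, 5 per tissue, held 2 arrays from independent replicate experiments, each labelled from 500 ng of RNA, and the number of arrays limits the precision. Values were log2 RMA expression values and ran from 2.834 to 15.02. Replicate arrays correlated across probe sets with Pearson's r of 0.9915 to 0.9958. Arrays of submerged and dark tissue of the same duration correlated with r of 0.984 to 0.9908 in roots and 0.9766 to 0.982 in shoots. Light arrays correlated with the dark and submerged arrays of their tissue with r of 0.898 to 0.929 in roots and 0.8464 to 0.8829 in shoots. Probe sets are not independent replicates in any of these correlations. Changes below are log2 differences between group means with the standard error (SE) of the limma fit, and group means carry the SD of 2 arrays.

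Submergence for 7 h asked what roots express when water is added to darkness. The low-oxygen programme was raised in these roots, with its trihelix repressor HRA1 among the largest rises. Pyruvate decarboxylase PDC2 and lactate dehydrogenase LDH1, which carry fermentation, rose too, as did RTE1, a regulator of ethylene receptors. BCAT4, an enzyme of methionine chain elongation for glucosinolates, also rose. Expansins, which loosen cell walls, moved both ways. AT4G10270, of a wound-responsive family, rose most, from 4.94 ± 0.30 to 10.83 ± 0.23, a change of 5.89 (SE 0.34, adjusted p = 2.5e-08). HRA1 rose from 4.77 ± 0.09 to 9.16 ± 0.20, a change of 4.39 (SE 0.25, adjusted p = 2.5e-08). AT2G17850 rose by 4.77 (SE 0.44, adjusted p = 3.2e-06) and BCAT4 by 2.93 (SE 0.19, adjusted p = 6.4e-08). The calmodulin-like gene CML38 rose by 3.07 (SE 0.68, adjusted p = 0.009). Its call ended without dark replicate 1, without submerged replicate 2 and with a variance trend and robust estimation (adjusted p = 0.055). Its root arrays read 6.352 and 6.702 in darkness and 9.43 and 9.755 under water. The light shoot arrays, whose spread enters its SE in every comparison, read 5.161 and 8.436.

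In the core low-oxygen list 17 of 21 genes rose in these roots and 0 fell, with the same counts when adjusted over the list alone. The mean change was 2.29, above that of other genes (adjusted p = 1.4e-30, and 5.8e-33 to 0.031 over its alternatives, highest with an estimated correlation). The 4 genes that did not pass were AT1G26270 (0.12), AT5G45960 (0.05), AT5G42200 (0.00) and AT1G19530 (0.63). Both measured fermentation genes rose, LDH1 by 1.72 (SE 0.16, adjusted p = 3.1e-06) and PDC2 by 1.66 (SE 0.20, adjusted p = 4.5e-05), and RTE1 rose by 0.92 (adjusted p = 0.00058). Of 9 wall-loosening genes 3 rose and 2 fell over all probe sets, against 4 and 3 adjusted over the list alone. EXPA7 rose by 1.14 (adjusted p = 0.0013) while EXPA15 fell by 1.28 (adjusted p = 0.002), and the list did not pass (mean 0.25, adjusted p = 0.31), though it did without submerged replicate 1 (0.024). Outside the list the beta-expansin EXPB2 fell by 1.63 (adjusted p = 0.00034). Autophagy genes of the ATG8 family rose slightly as a list, 2 of 9 both over all probe sets and adjusted over the list alone, by a mean of 0.27 (adjusted p = 0.0071, and 0.0031 to 0.55 over its alternatives, highest with an estimated correlation). That call was also lost without submerged replicate 2 (adjusted p = 0.06) and with fry (0.096). The 10 measured of 39 listed genes of sucrose cleavage and glycolysis had a mean of −0.28, with 0 called either way. They passed as a lower list (adjusted p = 0.0086, and 0.0019 to 0.52 over its alternatives, highest with an estimated correlation). That call was lost without dark replicate 2, when the mean was −0.197. SUS1 and SUS4 of that list had no 1-gene probe set, so the test does not cover them.

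Across all probe sets 1005 were higher and 971 lower in submerged than in dark roots at 7 h, 1976 in total. Among probe sets naming 1 gene the falls included AT2G41190, by 1.90 (SE 0.30, adjusted p = 0.00074), and AT5G38710, by 1.87 (SE 0.20, adjusted p = 1.9e-05). The plastid genes psaI and matK fell by 1.94 (adjusted p = 0.016) and 1.76 (adjusted p = 0.017). Both calls ended without dark replicate 2 (adjusted p = 0.18 for psaI and 0.15 for matK), without submerged replicate 2 (0.26 and 0.28) and with a variance trend and robust estimation (0.077 and 0.079). The total was 1172 without dark replicate 1, 1263 without dark replicate 2, 1122 without submerged replicate 1 and 693 without submerged replicate 2.

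After 24 h the low-oxygen genes were still raised in submerged roots. Roots carried more of the fermentation transcripts PDC2 and LDH1 than dark roots of the same age. They carried less of the lectin gene EULS3. AT4G10270 rose from 6.34 ± 0.68 to 11.74 ± 0.30, by 5.40 (SE 0.34, adjusted p = 9.5e-08), and HRA1 from 5.27 ± 0.11 to 9.57 ± 0.73, by 4.3 (SE 0.25, adjusted p = 5.2e-08). AT2G17850 rose by 5.25 (SE 0.44, adjusted p = 1.3e-06). PDC2 rose by 2.5 and LDH1 by 2.05, each with an adjusted p of 6.3e-07. CML38 rose by 3.08 (adjusted p = 0.016), a call that ended without dark replicate 1 (0.067), dark replicate 2 (0.12) or submerged replicate 2 (0.17) and with a variance trend and robust estimation (0.094). Of the falls, AT3G53980 lost 2.28 (SE 0.23, adjusted p = 1.3e-05) and EULS3 lost 1.78 (SE 0.14, adjusted p = 6.3e-07). PYK10, a beta-glucosidase of root endoplasmic reticulum bodies, fell by 0.89 (adjusted p = 0.0073), a call that ended without dark replicate 2 (0.067) or submerged replicate 2 (0.16).

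The core low-oxygen list again had 17 of 21 genes up and 0 down in roots at 24 h, and 18 up adjusted over the list alone, with a mean of 2.49 (adjusted p = 3.7e-46, and 4.1e-52 to 0.0072 over its alternatives, highest with an estimated correlation). Among the 4 genes short of the threshold, AT2G15880 changed by 0.85 (adjusted p = 0.13), AT1G19530 by 0.32, AT5G42200 by 0.19 and AT5G45960 by 0.02. Wall loosening passed as a list with a mean of 0.40, while 0 of its 9 genes were called over all probe sets and 5 rose adjusted over the list alone (adjusted p = 0.024, and 0.0052 to 0.32 over its alternatives, highest with an estimated correlation). It was lost without dark replicate 2 (0.1), without submerged replicate 1 (0.15) and with fry (0.12). The 3 nucleolar genes of ribosome assembly had a mean of 0.39, with 0 called over all probe sets and 2 up adjusted over the list alone (adjusted p = 0.016, and 0.0052 to 0.18 over its alternatives, highest with an estimated correlation), lost without submerged replicate 1 (0.055). Sugar-starvation genes had a mean of −0.25 with 1 of 6 down (adjusted p = 0.021, and 0.00048 to 0.49 over its alternatives). That last call was lost with an estimated correlation (0.33), without dark replicate 1 (0.49) and without submerged replicate 1 (0.055). In all, 316 probe sets were higher and 416 lower, 732 together. Without dark replicate 1 there were 313, without submerged replicate 1 there were 423, and without submerged replicate 2 there were 275.

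Shoots held under water for 7 h raised much of the low-oxygen programme and, among genes that did not pass in roots, M10 of the late embryogenesis abundant family, the calmodulin-like gene CML41 and the receptor kinase gene SD1-29. The cold-regulated genes COR15A and COR15B, which encode chloroplast-protecting proteins, fell steeply. The auxin genes IAA29, a repressor of auxin responses, and GH3.3, which conjugates auxin, fell with them. AT4G10270 rose from 4.74 ± 0.08 to 10.29 ± 0.60, by 5.55 (SE 0.34, adjusted p = 4.9e-09), and M10 rose by 4.74 (SE 0.23, adjusted p = 3.4e-10). STR18, a sulfurtransferase gene, rose by 4.05 (SE 0.13, adjusted p = 3.8e-12), CML41 by 3.44 (adjusted p = 2.2e-09) and SD1-29 by 3.07 (adjusted p = 1.7e-08). COR15B fell from 9.39 ± 0.39 to 5.16 ± 0.35, by 4.22 (SE 0.19, adjusted p = 1.1e-10), and COR15A from 10.85 ± 0.07 to 7.00 ± 0.23, by 3.85 (SE 0.16, adjusted p = 6.9e-11). IAA29 fell by 4.00 (adjusted p = 6e-09), GH3.3 by 2.82 (adjusted p = 2.2e-07) and the dehydrin gene COR47 by 1.69 (adjusted p = 9e-08).

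In shoots at 7 h 16 of 21 core low-oxygen genes rose and 0 fell, 17 rising adjusted over the list alone, with a mean of 1.77 (adjusted p = 3.7e-18, and 7.2e-22 to 0.15 over its alternatives, highest with an estimated correlation). AT1G33055 rose by 3.05 (adjusted p = 5e-08), AT2G17850 by 2.84 (adjusted p = 0.00019) and HRA1 by 1.99, from 4.73 ± 0.21 to 6.73 ± 0.49 (adjusted p = 2.4e-05). PDC2 changed by 0.46 and did not pass (adjusted p = 0.15). Of 9 ATG8 genes 4 rose, also when adjusted over the list alone, among them ATG8B by 1.08 (adjusted p = 1.2e-05) and ATG8H by 0.93 (adjusted p = 0.00029). The ATG8 mean was 0.42 (adjusted p = 0.0014, and 0.00013 to 0.43 over its alternatives, highest with an estimated correlation). Sugar-starvation genes, already raised by darkness, had 2 of 6 genes further up and 3 adjusted over the list alone, with a mean of 0.36 (adjusted p = 0.0096, and 0.005 to 0.43 over its alternatives, highest with an estimated correlation), lost without dark replicate 1 (0.074). Of 9 photosynthesis genes 4 fell and 0 rose, with 5 down adjusted over the list alone and a mean of −0.58 (adjusted p = 0.0012, and 0.00032 to 0.43 over its alternatives, highest with an estimated correlation). The chlorophyll-binding gene LHCB4.2 led them with a fall of 1.08 (SE 0.21, adjusted p = 0.0014). Wall-loosening genes split, with 2 of 9 up and 3 down on both counts, all probe sets and adjusted over the list alone, and a mean of −0.21 (adjusted p = 0.22, but 0.031 with fry). EXPA8 fell by 1.48 (adjusted p = 3.8e-07) and XTH16, which remodels xyloglucan, rose by 1.1 (adjusted p = 0.0013).

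Probe sets called in shoots at 7 h numbered 3105, with 1482 higher and 1623 lower under water. The count was 1952 without dark replicate 1 and 1903 without submerged replicate 2. STOMAGEN, which encodes a peptide that promotes stomata, fell by 1.2 (SE 0.13, adjusted p = 5.3e-06), and PYK10 fell by 1.05 (adjusted p = 0.00037).

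By 24 h AT4G10270 was the sole core low-oxygen gene among the largest rises of 1-gene probe sets in submerged shoots, beside a receptor kinase and a peroxidase gene. The zinc finger gene ZAT10 and the immunity regulator WRKY53 rose. So did XTH16 and XTH33, of xyloglucan remodelling, and RTE1 of ethylene perception. COR15A, COR47 and the expansin gene EXPA16 fell. Among probe sets naming 1 gene AT3G46280 rose most, by 4.49 (SE 0.26, adjusted p = 3.5e-09), ahead of AT4G10270, which rose from 4.52 ± 0.15 to 8.85 ± 0.24, by 4.32 (SE 0.34, adjusted p = 1.1e-07). The peroxidase gene AT5G64120 rose by 3.98 (SE 0.31, adjusted p = 8.1e-08) and SD1-29 by 3.61 (SE 0.21, adjusted p = 4.4e-09). ZAT10 rose by 2.67 (SE 0.52, adjusted p = 0.0018). COR15A fell from 7.43 ± 0.10 to 4.77 ± 0.12, by 2.66 (adjusted p = 6.6e-09), EXPA16 by 3.11 (adjusted p = 1.2e-08) and AT1G30250 by 4.14 (SE 0.12, adjusted p = 9.9e-13).

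All 3 measured genes of the immunity list rose in shoots at 24 h, on both counts, over all probe sets and adjusted over the list alone, with a mean of 1.11 (adjusted p = 0.0014, and 0.00056 to 0.37 over its alternatives, highest with an estimated correlation). WRKY53 rose by 1.74 (SE 0.33, adjusted p = 0.0016) and WRKY6 by 1.1 (adjusted p = 0.0019, but 0.053 without dark replicate 1). WRKY22 rose by 0.49 (adjusted p = 0.029), a call lost without dark replicate 1 (0.093), dark replicate 2 (0.17), submerged replicate 1 (0.076) or submerged replicate 2 (0.16). The core low-oxygen list had 9 of 21 genes up and 1 down, 10 up and 1 down adjusted over the list alone, with a mean of 0.88 (adjusted p = 4.8e-07, and 1.9e-08 to 0.59 over its alternatives, highest with an estimated correlation, 0.052 with fry). Its rises included AT1G33055 by 1.95 (adjusted p = 1.1e-05) and AT1G19530 by 1.54 (adjusted p = 0.0025). AT5G42200 was the gene that fell, by 0.89 (adjusted p = 0.0022), named after its value was seen. HRA1 rose by 0.99 (adjusted p = 0.015), which ended without dark replicate 2 (0.15) or submerged replicate 1 (0.11). The oxidative stress list did not pass (adjusted p = 0.91), and its mean of 0.51, median of −0.23 and downward test differed in sign. Photosynthesis (mean −0.17, adjusted p = 0.88) and ATG8 genes (mean 0.00, adjusted p = 0.91) were not shifted as lists. Across the array 1343 probe sets were higher and 1369 lower, 2712 in all, and 1699 were called without dark replicate 1 and 1618 without dark replicate 2.

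**Figure D1:**
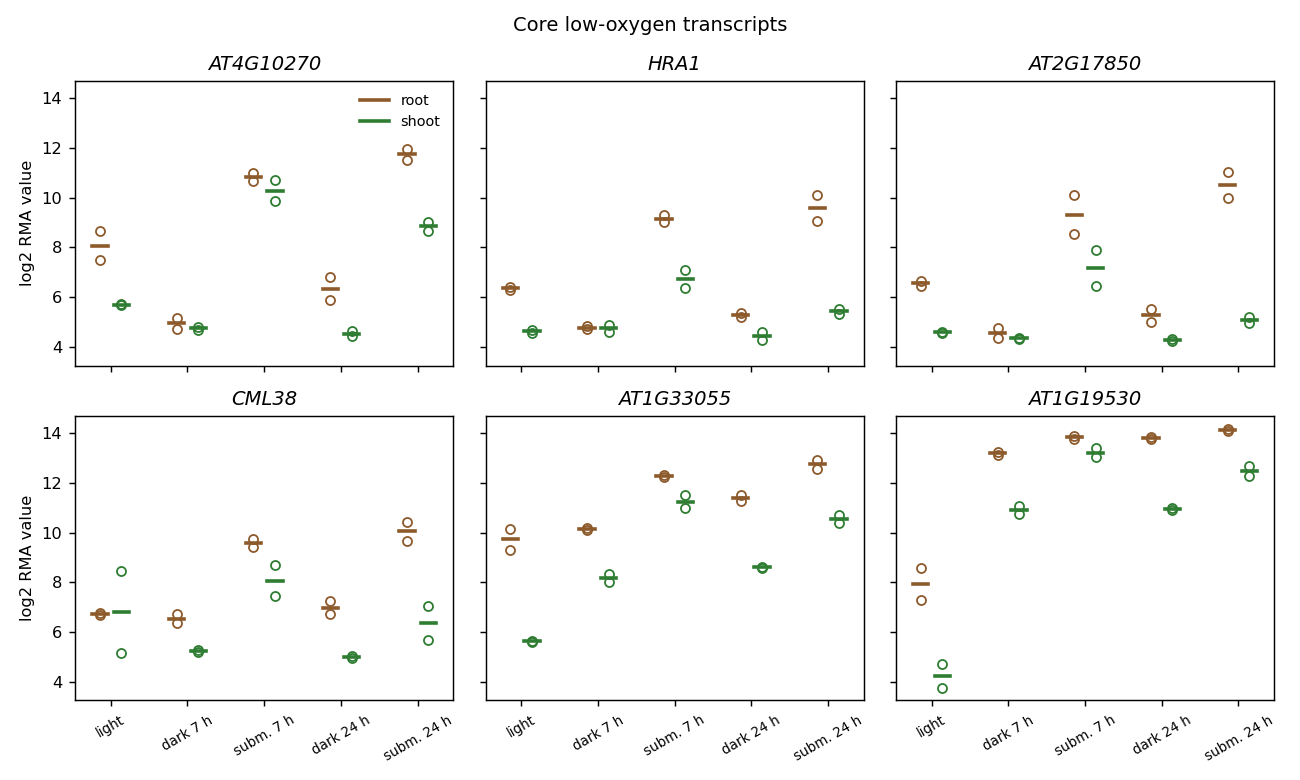
Log2 RMA expression values of 6 low-oxygen genes (AT4G10270, HRA1, AT2G17850, CML38, AT1G33055 and AT1G19530) in light, dark and submerged tissue, with open circles for single arrays, bars for group means, roots in brown and shoots in green. HRA1 reached 9.57 in submerged roots at 24 h and 5.43 in submerged shoots, while AT4G10270 was high in both.

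Roots and shoots were set against each other by testing the root change minus the shoot change. At 7 h HRA1, LDH1 and BCAT4 rose more in roots. M10, CML41 and SD1-29 rose in shoots and did not pass in roots. The cold genes COR15A and COR15B and the auxin repressor IAA29 fell in shoots. In roots COR15B stood at 4.3 in darkness and 4.41 under water and IAA29 at 4.43 in both, so low that no fall could have been measured there. The difference was 4.34 for COR15B (SE 0.26, adjusted p = 2.9e-08), 4.00 for IAA29 (SE 0.36, adjusted p = 1.7e-06) and 2.78 for BCAT4 (SE 0.27, adjusted p = 5.7e-06). It was −4.75 for M10 (SE 0.33, adjusted p = 1.3e-07) and −3.68 for CML41 (SE 0.28, adjusted p = 3.1e-07). HRA1 differed by 2.4 (adjusted p = 0.00041), LDH1 by 1.17 (adjusted p = 0.0029) and the pyruvate orthophosphate dikinase gene PPDK by −1.11 (adjusted p = 0.0033). In total 869 probe sets changed more upward in roots and 878 more upward in shoots, 1747 together, with 1156 left without root submerged replicate 2 and 1141 without shoot dark replicate 1.

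As lists, sugar starvation leaned to shoots at 7 h (mean −0.48, 2 of 6 genes called and 4 adjusted over the list alone), with an adjusted p of 0.012, and 0.0021 to 0.39 over its alternatives, highest with an estimated correlation. Wall loosening leaned to roots (mean 0.46, 4 of 9 genes up, with 4 up and 1 down adjusted over the list alone), with an adjusted p of 0.028, and 0.0012 to 0.39 over its alternatives, highest with an estimated correlation. That call was lost without root dark replicate 1 (0.14), without root submerged replicate 2 (0.19) and with fry (0.13). Core low-oxygen genes leaned to roots by a mean of 0.52 (3 of 21 up and 2 down, 4 and 3 adjusted over the list alone), with an adjusted p of 0.04, and 0.00037 to 0.73 over its alternatives, highest with an estimated correlation. The call was lost without root dark replicate 1 (0.14), root submerged replicate 2 (0.24), shoot dark replicate 2 (0.12) or shoot submerged replicate 1 (0.5), without the light arrays (0.056) and with fry (0.45).

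At 24 h the low-oxygen genes set the tissues apart. AT2G17850, HRA1, PDC2 and LDH1 rose more in roots, while AT3G46280, the peroxidase gene AT5G64120 and SD1-29 rose in shoots without a matching rise in roots. AT2G17850 differed by 4.44 (SE 0.62, adjusted p = 0.0002), HRA1 by 3.31 (SE 0.36, adjusted p = 1.5e-05), PDC2 by 2.34 (adjusted p = 3.2e-05) and LDH1 by 1.70 (adjusted p = 0.00011). AT5G64120 differed by −4.13 (SE 0.43, adjusted p = 1e-05) and stood at 11.53 in dark roots and 11.38 in submerged roots. AT3G46280 differed by −3.91 (adjusted p = 2.6e-06). It stood at 9.65 in dark and 10.23 in submerged roots, above its 4.18 and 8.67 in shoots. The core list had 12 of 21 genes higher in the root response and 0 lower, 13 and 1 adjusted over the list alone, with a mean of 1.61 (adjusted p = 6.3e-12, and 1.4e-16 to 0.43 over its alternatives, highest with an estimated correlation). Immunity genes leaned to shoots by −0.98, 1 of 3 called and 3 adjusted over the list alone (adjusted p = 0.021, and 0.0085 to 0.46 over its alternatives, highest with an estimated correlation). That call ended without root submerged replicate 1 (0.058), without shoot dark replicate 1 (0.066) and with fry (0.068). There were 1561 probe sets with a difference, 678 toward roots and 883 toward shoots. The large-subunit ribosomal RNA control also moved at 24 h, where submerged minus dark arrays gave 0.737 in roots and −0.5098 in shoots, with no overlap of arrays in either tissue. Without root dark replicate 1 there were 961, without root submerged replicate 2 there were 971, and without shoot dark replicate 2 there were 1012.

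How the response moved between 7 and 24 h was tested within each tissue as the change at 24 h minus the change at 7 h. The 2 times also differ in clock time, so duration and time of day cannot be told apart in these differences. Few genes differed in roots. BCAT4 rose at 7 h and did not pass at 24 h, when its dark control was higher (9.5 against 8.52) and submerged roots lower (9.81 against 11.44), and the core low-oxygen genes did not differ as a list. The difference for BCAT4 was −2.62 (SE 0.27, adjusted p = 0.00036), for AT3G23550 −1.83 (SE 0.27, adjusted p = 0.0035) and for AT2G43800 1.44 (SE 0.22, adjusted p = 0.0057), whose dark control fell from 7.91 to 6.43 while submerged roots stood at 6.73 and 6.68. ATG8 genes lay lower at 24 h, with 1 of 9 called and 3 adjusted over the list alone and a mean of −0.47 (adjusted p = 0.00021, and 1e-05 to 0.5 over its alternatives, highest with an estimated correlation, 0.094 with fry). Nucleolar genes lay higher, with 1 of 3 called and 2 adjusted over the list alone and a mean of 0.75 (adjusted p = 0.0018, and 0.00051 to 0.15 over its alternatives, highest with an estimated correlation). Glycolysis lay higher by a mean of 0.26 with 0 genes called (adjusted p = 0.03, and 0.0079 to 0.52 over its alternatives, highest with an estimated correlation), lost without dark 24 h replicate 1 (0.11), dark 7 h replicate 2 (0.2) or submerged 7 h replicate 1 (0.054) and with fry (0.13). Core low-oxygen genes had a mean of 0.20, with 0 called and 1 adjusted over the list alone (adjusted p = 0.53). That list passed without submerged 24 h replicate 1 (0.0049) or submerged 7 h replicate 2 (0.021). The 330 probe sets called were 134 up and 196 down. They numbered 91 with root arrays only, 77 without dark 24 h replicate 1, 190 without submerged 24 h replicate 1, 41 without submerged 24 h replicate 2 and 87 without submerged 7 h replicate 2.

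In shoots the low-oxygen list was raised less at 24 h than at 7 h. The cold gene COR15B and the auxin genes IAA29 and GH3.3 had fallen at 7 h and their falls at 24 h were smaller. For COR15B and GH3.3 the dark controls themselves were lower at 24 h, 5.76 against 9.39 and 6.93 against 9.02, which left less room to fall. The dark control of ECS1 was also lower at 24 h (8.23 against 10.33), and that of ATG8B higher (10.86 against 10.09) while submerged shoots went from 11.17 to 10.84. XTH33 turned from a fall to a rise, and the expansin gene EXPA8 no longer passed as a fall. The responses of AT4G15680 and the carboxypeptidase-like gene scpl23 shifted downward. COR15B differed by 3.26 (SE 0.26, adjusted p = 4.2e-06), IAA29 by 2.85 (SE 0.36, adjusted p = 0.00028) and ECS1 by 2.95 (SE 0.38, adjusted p = 0.00037). XTH33 differed by 1.91 (adjusted p = 0.00093) and EXPA8 by 1.64 (adjusted p = 0.00012). AT4G15680 differed by −3.39 (SE 0.28, adjusted p = 4.2e-06) and scpl23 by −3.07 (SE 0.21, adjusted p = 8.6e-07). The core list differed by a mean of −0.89, with 1 of 21 genes lower and 9 adjusted over the list alone (adjusted p = 3.4e-08, and 2.2e-13 to 0.29 over its alternatives, highest with an estimated correlation, 0.11 with fry). ATG8B differed by −1.11 (adjusted p = 0.0035), the gene of its list that passed, and the list by −0.42 (adjusted p = 0.00085, and 2.6e-05 to 0.29 over its alternatives, highest with an estimated correlation, 0.11 with fry).

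Other lists also shifted between the times in shoots, and each of these calls was lost with an estimated correlation and with fry. Sugar starvation differed by a mean of −0.38, with 0 of 6 genes called and 1 lower adjusted over the list alone (adjusted p = 0.0033, and 0.00077 to 0.29 over its alternatives, highest with an estimated correlation, 0.1 with fry). Photosynthesis differed by 0.41, with 0 of 9 genes called and 1 higher adjusted over the list alone (adjusted p = 0.01, and 0.0033 to 0.37 over its alternatives, highest with an estimated correlation), lost without dark 7 h replicate 2 (0.053) and with fry (0.26). Wall loosening differed by 0.33 with 2 of 9 genes higher (adjusted p = 0.029, and 0.02 to 0.29 over its alternatives, highest with an estimated correlation). It was lost without dark 24 h replicate 1 (0.062), submerged 24 h replicate 2 (0.051) or submerged 7 h replicate 2 (0.058), without the light arrays (0.066) and with fry (0.11). Immunity genes differed by 0.79, with 0 of 3 called and 2 higher adjusted over the list alone (adjusted p = 0.01, and 0.004 to 0.29 over its alternatives, highest with an estimated correlation), lost without dark 24 h replicate 1 (0.062) or dark 7 h replicate 2 (0.083) and with fry (0.11). Single probe sets numbered 456, 260 up and 196 down. Leaving out an array gave 224 (dark 24 h replicate 1), 176 (dark 24 h replicate 2), 264 (dark 7 h replicate 1), 214 (dark 7 h replicate 2), 220 (submerged 24 h replicate 2), 248 (submerged 7 h replicate 1) and 229 (submerged 7 h replicate 2).

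Genes that answered submergence in more than 1 tissue or at both times were counted from the calls. AT4G10270, HRA1, AT1G33055 and RTE1 are examples, low-oxygen genes and a gene of ethylene perception. At 7 h 291 probe sets were higher and 221 lower in both roots and shoots, 512 together, where independent lists would share 65.5 and 69.3. A further 77 were called in opposite directions, against 135 by chance. At 24 h 82 were higher and 94 lower in both tissues, 176 together, against 18.66 and 25.04, and 41 moved oppositely against 43.6. Between the times, roots shared 301 calls (162 up and 139 down, against 13.96 and 17.76) and shoots 1398 (759 up and 639 down, against 87.5 and 97.7). The overlap at 7 h was 305 without root dark replicate 1, 307 without root submerged replicate 1, 227 without root submerged replicate 2 and 324 without shoot submerged replicate 2. At 24 h it was 104 without root dark replicate 1 and 86 without root submerged replicate 2. Between the times in roots it was 176 without dark 24 h replicate 1, 182 without submerged 24 h replicate 1, 160 without submerged 24 h replicate 2 and 185 without submerged 7 h replicate 2.

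**Figure D2:**
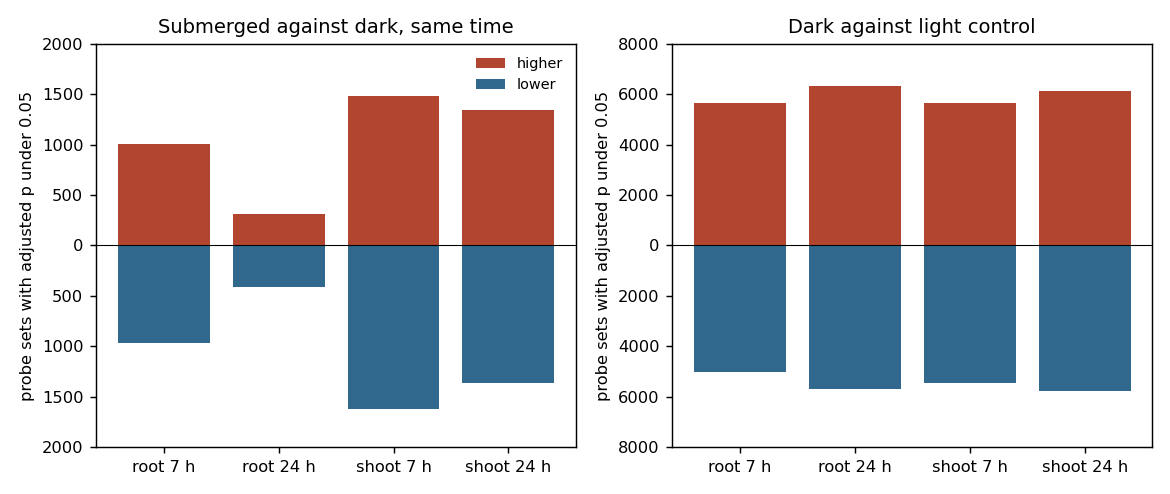
Number of probe sets called higher and lower (adjusted p under 0.05) in submerged against dark tissue and in dark against light tissue, as bars for roots and shoots at 7 and 24 h. Submergence gave 732 to 3105 calls and darkness 10660 to 12016.

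Darkness alone was compared with light at 0 h to give the background on which submergence acted. At 7 h the dark harvest fell at another clock time than the light harvest, in both tissues. The light arrays also stood apart in the large-subunit ribosomal RNA control, which was 3.2 lower in light roots and 1.914 lower in light shoots than in the dark and submerged arrays, with all 8 of these above both light arrays in each tissue. Dark roots raised genes that break down amino acids, among them MCCA and IVD of leucine breakdown, ASPGB1, an asparaginase, and MGL, a methionine gamma-lyase. PPDK, which recovers carbon from pyruvate, and the kinase subunit gene AKINBETA1 rose as well. Wall-loosening genes fell throughout, with XTH19 and EXPA18 among the steepest. BCAT4 of glucosinolate synthesis fell, as did PYK10. At 7 h ASPGB1 rose by 6.05 (SE 0.29, adjusted p = 3.1e-11), PPDK by 5.63 (SE 0.15, adjusted p = 5.7e-14) and MCCA from 8.89 ± 0.00 to 13.12 ± 0.21, by 4.23 (SE 0.12, adjusted p = 7.4e-14). XTH19 fell by 4.54 (SE 0.37, adjusted p = 1.7e-08) and BCAT4 by 3.74 (SE 0.19, adjusted p = 7.4e-11). At 24 h MGL rose by 6.84 (SE 0.23, adjusted p = 3.5e-13), and XTH19 fell by 5.40 (adjusted p = 1.1e-09) and PYK10 by 2.13 (adjusted p = 1.2e-08). The clock gene GI rose by 1.88 at 7 h (adjusted p = 3.6e-07), where darkness cannot be told apart from time of day.

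All 6 measured sugar-starvation genes, of 26 listed, rose in dark roots at both times. Their mean rise was 3.15 at 7 h (adjusted p = 4.8e-08, and 1.8e-11 to 0.026 over its alternatives, highest with an estimated correlation). At 24 h it was 2.85 (adjusted p = 3.7e-06, and 4.6e-11 to 0.06, highest again with an estimated correlation). All 9 wall-loosening genes fell, by means of 2.76 (adjusted p = 4.8e-08, and 6.2e-09 to 0.018 over its alternatives) and 3.18 (adjusted p = 1.4e-07, and 1.5e-09 to 0.021 over its alternatives). Photosynthesis genes rose as a list at 7 h, 6 of 9 with a mean of 1.35 (adjusted p = 0.0077, and 7.1e-05 to 0.53 over its alternatives, highest with an estimated correlation). PSAN rose by 3.44 (SE 0.25, adjusted p = 5.7e-09), LHCB4.1 by 2.84 (SE 0.16, adjusted p = 2e-10) and LHCB4.2 by 2.11 (SE 0.21, adjusted p = 2e-07), a rise that equalled 1.195% of the LHCB4.2 level in dark shoots on the linear scale. At 24 h 3 of 9 were up and the list did not pass (mean 1.12, adjusted p = 0.08), though it did without light replicate 2 (0.011) and with fry (0.00014). Of 9 ATG8 genes 7 rose and 1 fell at 24 h, with a mean of 0.72 (adjusted p = 0.041, and 9.5e-05 to 0.5 over its alternatives, highest with an estimated correlation). Glycolysis fell in 7 of 10 genes and rose in 1, or 2 adjusted over the list alone, with a mean of −0.37 (adjusted p = 0.041, and 0.00031 to 0.34). It included PFPB1, which fell by 2.36 (adjusted p = 1.3e-10). Of 3 nucleolar genes 2 fell, with a mean of −1.14 (adjusted p = 0.041, and 4.3e-06 to 0.29). Those 3 list calls at 24 h were each lost without dark replicate 1 (0.055) or light replicate 1 (0.05) and with an estimated correlation (0.5 for ATG8, 0.34 for glycolysis and 0.29 for the nucleolar list). Core low-oxygen genes split, 6 up and 8 down of 21 at 7 h (mean −0.06, adjusted p = 0.73). At 7 h the mean and the median of 2 lists differed in sign, glycolysis with 0.17 and −0.35 (downward test, adjusted p = 0.36) and starch with 0.76 and −0.04 (upward test, adjusted p = 0.34, but 3.5e-05 with fry). Called probe sets numbered 10660 at 7 h (5640 up and 5020 down) and 12016 at 24 h (6331 up and 5685 down), and the comparisons share their light arrays.

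Dark shoots raised the leucine breakdown genes MCCA and IVD and the measured autophagy genes of the ATG8 family. They lowered anthocyanin genes such as DFR, photosynthesis genes such as LHCB4.3, and the regulator of stomatal lineage SPCH. MCM7, of DNA replication, and the measured genes of ribosomal proteins and of the nucleolus fell too. MCCA rose from 7.40 ± 0.02 to 13.33 ± 0.06 at 7 h, by 5.93 (SE 0.12, adjusted p = 2.4e-16), and by 6.01 at 24 h (adjusted p = 1.9e-16). IVD rose by 5.95 (adjusted p = 3.3e-16) and 5.69 (adjusted p = 3.9e-16). TBL26, of a family that acetylates wall polymers, fell by 6.91 (SE 0.17, adjusted p = 1.7e-15) and 6.66 (adjusted p = 2e-15). DFR fell by 4.41 (adjusted p = 5.7e-14) and 4.2 (adjusted p = 9.2e-14), and LHCB4.3 by 2.24 (adjusted p = 2.7e-10) and 5.31 (adjusted p = 3.7e-15). MCM7 fell by 1.89 (adjusted p = 5.9e-09) and 2.99 (adjusted p = 1.1e-11), and SPCH by 1.59 (adjusted p = 1e-07) and 1.95 (adjusted p = 5.5e-09). EIN3 of ethylene signalling rose by 2.47 (adjusted p = 2.2e-11) and 2.71 (adjusted p = 5.4e-12). BCAT4 fell by 5.99 (adjusted p = 5.2e-14) and 5.83 (adjusted p = 6.5e-14).

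Lists showed the same division in dark shoots. All 6 measured sugar-starvation genes, of 26 listed, rose. Their mean rise was 4.39 at 7 h (adjusted p = 4.5e-08, and 6.6e-13 to 0.026 over its alternatives). At 24 h it was 4.29 (adjusted p = 5.3e-07, and 8e-13 to 0.041 over its alternatives). All 9 ATG8 genes rose, by means of 2.47 (adjusted p = 4.5e-08, and 2.2e-09 to 0.1 over its alternatives, highest with an estimated correlation) and 2.48 (adjusted p = 5.3e-07, and 2e-09 to 0.14, highest again with an estimated correlation). ATG8B rose by 3.61 (adjusted p = 1.8e-13) and 4.38 (adjusted p = 1.5e-14). The 3 measured anthocyanin genes, of 20 listed, fell. Their mean fall at 7 h was 3.61 (adjusted p = 0.00027, and 8.8e-13 to 0.026 over its alternatives). At 24 h it was 3.53 (adjusted p = 0.00072, and 1.2e-12 to 0.041 over its alternatives). Shoot cell markers fell in 3 of 5 genes at 7 h, with a mean of −0.99 (adjusted p = 0.045, and 2.3e-05 to 0.32 over its alternatives, highest with an estimated correlation), lost without light replicate 1 (0.093), and again in 3 of 5 at 24 h, 4 adjusted over the list alone, with a mean of −1.14.

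At 24 h 4 of 9 photosynthesis genes fell in dark shoots, 3 adjusted over the list alone, with a mean of −1.34. At 7 h 3 of 9 fell and the mean was −0.62 (adjusted p = 0.12, but 0.0041 with fry), and the times were not tested against each other. All 4 measured ribosomal protein genes, of 22 listed, fell, with a mean of −0.99, among them RPL4D by 1.91 (adjusted p = 2.2e-10). All 3 measured nucleolar genes, of 10 listed, fell, with a mean of −1.33, among them NOP58-2 by 1.92 (adjusted p = 3.4e-09). The photosynthesis, ribosomal, nucleolar and shoot marker lists each had an adjusted p of 0.023 at 24 h and were lost with an estimated correlation. Over their alternatives adjusted p ran from 8.1e-06 to 0.45 for photosynthesis, from 5e-07 to 0.26 for ribosomal proteins, from 4.5e-07 to 0.19 for nucleolar genes and from 8.9e-06 to 0.26 for shoot markers, highest with an estimated correlation. Wall-loosening genes did not pass at 24 h (adjusted p = 0.95), and their mean of −0.12, median of 0.38 and upward test differed in sign. Called probe sets numbered 11130 at 7 h (5665 up and 5465 down) and 11926 at 24 h (6144 up and 5782 down), and the comparisons share their light arrays.

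**Figure D3:**
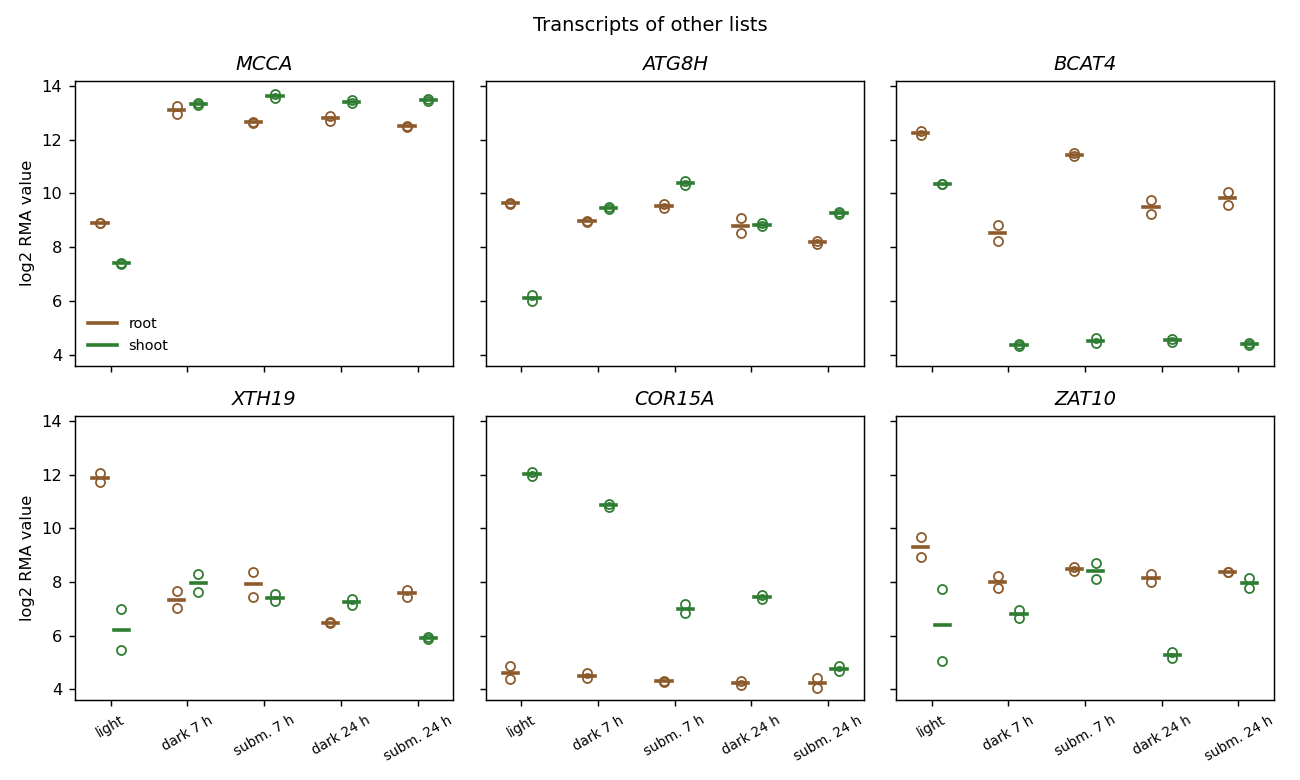
Log2 RMA expression values of MCCA, ATG8H, BCAT4, XTH19, COR15A and ZAT10 in light, dark and submerged tissue, with open circles for single arrays, bars for group means, roots in brown and shoots in green. COR15A stood at 10.85 in dark shoots at 7 h, 7.00 in submerged shoots at 7 h and 4.77 in submerged shoots at 24 h.

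Roots and shoots harvested in the light differed as organs do. HPR, a gene of photorespiration, and SBPASE of the Calvin cycle were lower in roots. The peroxidase gene AT3G01190 and AT1G26250 marked roots. All 9 photosynthesis genes were lower in roots, by a mean of 7.95 (adjusted p = 2.2e-09, and 7.7e-12 to 0.057 over its alternatives, highest with an estimated correlation). HPR was lower by 8.90 (SE 0.31, adjusted p = 2.2e-14) and SBPASE by 8.84 (SE 0.16, adjusted p = 2.8e-17), and AT4G33720 was higher by 7.84 (SE 0.45, adjusted p = 3e-11). In light roots SBPASE stood at 4.236, so low that its true difference may be larger. Shoot cell markers were lower in all 5 genes, with a mean of −5.37 (adjusted p = 6.8e-05, and 3.5e-11 to 0.057), anthocyanin in all 3, with a mean of −3.81 (adjusted p = 0.0013, and 1.1e-12 to 0.057), and starch in 4 of 5, with a mean of −1.63 (adjusted p = 0.0067, and 1.2e-08 to 0.14). ATG8 genes were higher in 8 of 9, with a mean of 1.58 (adjusted p = 0.0013, and 1.5e-07 to 0.28). Wall loosening was higher in 7 of 9 and lower in 1, with a mean of 2.75 (adjusted p = 0.0067, and 1.2e-08 to 0.14). Core low-oxygen genes were higher in 15 of 21 and lower in 2, with a mean of 1.51 (adjusted p = 0.0067, and 0.00015 to 0.43). The 2 lower genes were PDC2 (−0.82) and AT5G45960 (−2.25), named after their values were seen. The last value of each range was that with an estimated correlation, with which 0 of the 7 lists passed. In the light 7927 probe sets were higher in roots and 5522 lower, 13449 in all, but after median centring 6680 were higher and 8131 lower.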

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

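The tests of explanations in the next 3 paragraphs were chosen only after the results were seen. The comparisons behind them and the core list test with its estimated correlation and fry were planned. So were the fits without single arrays and the differences between tissues and times that follow. The bounds that the tests of explanations and the fits without single arrays were held to were set afterwards.

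Darkness called 10660 to 12016 of 22746 probe sets, about as many as it left uncalled, and submergence at most 3105. Marked degradation of RNA was argued against by the 3' minus 5' signal of the actin and GAPDH controls. Dark or submerged arrays differed from light arrays by at most −0.2835, for actin in roots, against a pooled replicate SD of 0.1409. The light root arrays read 1.621 and 1.91 there and the other root arrays 1.209 to 1.743, so a small difference in roots stays open. A shift in time of day was argued against as the whole cause, because calls at 24 h, the clock time of the light harvest, were 1.072 times those at 7 h or more. Separate handling of the light arrays cannot be told apart from darkness, because large-subunit ribosomal RNA signal was higher outside the light by 3.2 in roots and 1.914 in shoots while the hybridization spikes differed by 0.02 and −0.07. The sugar loss that darkness brings stays open beside it as an untested biological difference.

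The transcripts LHCB4.1, LHCB4.2 and PSAN of the photosystems rose in darkened roots, where shoot tissue in the root samples might be a source. With the share of shoot RNA set by these 3 transcripts (a median of 3.199% at 7 h and 4.193% at 24 h), the other 5 photosynthesis transcripts stood at a median of −2.37 and −2.53 relative to the level that share would give, and at −1.22 (replicate SD 0.52) and −1.77 with the lowest of the 3 shares. With the share set by all called risers of the list, 23 transcripts abundant in dark shoots stood at a median of −1.17 at 24 h, 13 of them lower by more than 1, against a replicate SD of 0.16, and at 7 h, with that share at 0.9437%, at −0.27 against an SD of 0.29. With the lowest share (1.195% at 7 h and 2.128% at 24 h) the 23 stood at −0.5 and −0.39, with 7 and 11 lower by more than 1. A share of shoot RNA would raise every transcript abundant in shoots. At 24 h PRK, PSAE1 and PSBW stood at 4.287, 5.598 and 5.843 in dark roots against 4.452, 5.611 and 5.842 in light roots. RCA and SBPASE were higher, at 6.817 against 6.098 and 4.429 against 4.236. At 24 h the 5 transcripts thus lay below what shoot tissue as the whole source of the 3 rises would give, while the 23 transcripts divided. The 5 were those left after the risers of the list had set the share. The rule, set after the values were seen, asked every one of these medians to lie lower by more than 1. The −0.39 did not, so the test cannot decide at 24 h, and shoot tissue as a part or the whole source stays open. At 7 h shoot tissue cannot be told apart from a rise in root cells.

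The core low-oxygen list was less raised in submerged shoots at 24 h than at 7 h, by a mean of −0.89 (adjusted p = 3.4e-08, and 2.2e-13 to 0.29 over its alternatives), a call lost with an estimated correlation (0.29) and with fry (0.11). A rise of the list in the 24 h dark controls was argued against, because its median change from 7 to 24 h was −0.0084 in dark shoots and −1.09 in submerged shoots. A single array as the whole cause was argued against by leaving out each shoot array in turn. The mean nearest to 0 was −0.54, without submerged 7 h replicate 2, so part of the −0.89 rested on that array. The values were −1.24 without submerged 7 h replicate 1, −1.07 without submerged 24 h replicate 1 and −0.71 without submerged 24 h replicate 2. A fading of the shoot response between the times is a candidate explanation and remains a hypothesis. The harvests at 7 and 24 h fell at different clock times, so a response that varies with time of day cannot be told apart from it.

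The response to submergence differed between roots and shoots at 7 h for 1747 probe sets and at 24 h for 1561. At 7 h COR15B (4.34) and IAA29 (4.00) fell in shoots, while in roots they stood at 4.3 and 4.43 in darkness, too low for a fall to be measured. M10 (−4.75) and CML41 (−3.68) rose in shoots and did not pass in roots. Core low-oxygen genes (0.52) and wall loosening (0.46) leaned to roots and sugar starvation (−0.48) to shoots at that time. These 3 list calls were lost with an estimated correlation (adjusted p = 0.73, 0.39 and 0.39). The low-oxygen call also ended without root dark replicate 1 (0.14), root submerged replicate 2 (0.24), shoot dark replicate 2 (0.12) or shoot submerged replicate 1 (0.5), without the light arrays (0.056) and with fry (0.45). The wall call also ended without root dark replicate 1 (0.14) or root submerged replicate 2 (0.19) and with fry (0.13). At 24 h AT2G17850 (4.44) and AT5G10040 (4.02) rose more in roots. AT5G64120 (−4.13) and AT3G46280 (−3.91) rose in shoots without a matching rise in roots. The call of AT5G10040 (adjusted p = 0.019) ended without root dark replicate 1 (0.068), root submerged replicate 2 (0.11), shoot dark replicate 1 (0.058), shoot dark replicate 2 (0.063) or shoot submerged replicate 2 (0.076), and with a variance trend and robust estimation (0.098). Core low-oxygen genes leaned to roots at 24 h by 1.61 and immunity genes to shoots by −0.98, and both calls were lost with an estimated correlation (0.43 and 0.46). The immunity call also ended without root submerged replicate 1 (0.058), without shoot dark replicate 1 (0.066) and with fry (0.068).

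Between 7 and 24 h the response differed for 330 probe sets in roots and 456 in shoots. In roots BCAT4 (−2.62), as its dark control rose from 8.52 to 9.5, and AT3G05950 (−2.24) were raised less at 24 h, the second with an adjusted p of 0.0076 that reached 0.05 without submerged 24 h replicate 2. The dark control of AT3G05950 rose from 9.19 to 11.86 between the times while submerged roots stood at 11.96 and 12.39, so its smaller response came with the rise of the control. EXPB2 (1.69, adjusted p = 0.022) and the plastid gene petB (1.62, adjusted p = 0.045) moved the other way in roots, and both calls ended with root arrays only (0.081 and 0.13). For EXPB2 roots stood at 6.73 in darkness and 5.1 under water at 7 h but at 4.93 and 4.99 at 24 h, when the control was too low for a fall to be measured. The call of EXPB2 also ended without replicate 1 of dark 24 h (0.076), dark 7 h (0.067), submerged 24 h (0.076) or submerged 7 h (0.061), and without submerged 7 h replicate 2 (0.056). That of petB ended without dark 24 h replicate 1 (0.15) or 2 (0.077), dark 7 h replicate 2 (0.13), submerged 24 h replicate 1 (0.096) or 2 (0.16), or submerged 7 h replicate 2 (0.19), and with a variance trend and robust estimation (0.1). Glycolysis (0.26) and nucleolar genes (0.75) lay higher in roots at 24 h and ATG8 genes (−0.47) lower, calls that were all lost with an estimated correlation (0.52, 0.15 and 0.5). Glycolysis was also lost without dark 24 h replicate 1 (0.11), dark 7 h replicate 2 (0.2) or submerged 7 h replicate 1 (0.054) and with fry (0.13), and ATG8 with fry (0.094). In shoots COR15B (3.26) and ECS1 (2.95) shifted upward, COR15B as its dark control fell from 9.39 to 5.76 and submerged shoots stood at 5.16 and 4.8, ECS1 as its control fell from 10.33 to 8.23, and AT4G15680 (−3.39) and scpl23 (−3.07) downward. As lists in shoots, photosynthesis (0.41), wall loosening (0.33) and immunity genes (0.79) shifted upward, and core low-oxygen (−0.89), sugar starvation (−0.38) and ATG8 genes (−0.42) downward. All 6 of these calls were lost with an estimated correlation (adjusted p from 0.29 to 0.37) and with fry (from 0.1 to 0.26). Photosynthesis also ended without dark 7 h replicate 2 (0.053), wall loosening without dark 24 h replicate 1 (0.062), submerged 24 h replicate 2 (0.051), submerged 7 h replicate 2 (0.058) or the light arrays (0.066), and immunity without dark 24 h replicate 1 (0.062) or dark 7 h replicate 2 (0.083).

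The large-subunit ribosomal RNA control, in data outside the comparisons, was 3.2 higher in dark and submerged than in light roots and 1.914 higher in shoots, with all 8 arrays above both light arrays in each tissue. At 24 h its submerged minus dark difference was 0.737 in roots and −0.5098 in shoots, with no overlap of arrays in either tissue. Whether this bore on the calls at 24 h was not tested.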

How the results depend on the processing

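Of the settings and tests in this part, the fits without light arrays, the leave-one-out overlaps and the family tests were chosen after results were seen. Changes of log2 0.5 were mostly not called in the simulation, which changed fewer probe sets than any real comparison called. Signal near background limits the dimmest probe sets. In leave-one-out fits the lone array of a group was assumed to vary like the other groups.

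Of 477 named-gene calls, 386 held under every setting but the 2-fold minimum, 91 were lost at least once and 0 changed sign. Leave-one-out fits lost 301 of 2224, 1-tissue fits 24 of 422, a variance trend with robust estimation 16, quantile normalization 11, median centring 9, the replicate block 7, that block within each tissue 10, 1-gene probe sets 4, the fit without light arrays 1 of 232 and the dim filter 0 of 462. The 2-fold minimum lost 90 by its construction. Of 53 list calls, 44 were lost with an estimated correlation, 14 with fry, 32 of 268 in leave-one-out fits and 2 of 27 without light arrays. None was lost under the scalings, the block or all probe sets of a gene, 31 held under every setting but an estimated correlation, and 9 held with it too. List results that had not been called passed in 37 cases with fry and 17 in leave-one-out fits. In 1 case each they passed with the replicate block and without light arrays (photosynthesis in the 7 h tissue difference, adjusted p = 0.046 and 0.036), with quantile normalization (ATG8 in submerged roots at 24 h, 0.026) and with median centring (immunity between the tissues in light, 0.048). For the losses not made by construction or by fewer arrays, the cause was not tested.

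Asking also for 2-fold, submergence gave 374 calls in roots at 7 h (264 up and 110 down, against 1005 and 971 without that minimum), 213 in roots at 24 h (105 and 108), 862 in shoots at 7 h (473 and 389) and 754 in shoots at 24 h (461 and 293). Darkness gave 4143 (1917 up and 2226 down, against 5640 and 5020) and 5341 (2413 and 2928, against 6331 and 5685) in roots and 5540 (2784 and 2756) and 6361 (3167 and 3194) in shoots. Tissue differences gave 880 (456 up and 424 down) and 852 (328 and 524), time differences 194 in roots (54 up and 140 down) and 270 in shoots (149 and 121), and the tissues in light 7121. Shared calls fell to 82 between tissues at 7 h (69 up and 13 down, against 291 and 221), 40 at 24 h (24 and 16), 101 between times in roots (69 and 32) and 416 in shoots (274 and 142).

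With 1-gene probe sets, fewer were tested. The counts, in the same order, were 958, 359, 1539 and 1298 for submergence, 5758, 6620, 6006 and 6475 for darkness, 835 and 749 for tissue differences, 163 and 208 for time differences and 7379 in light. With root arrays only, the time difference in roots gave 91 calls.

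Leaving out 1 array at a time, submergence gave 693 to 1263 calls in roots at 7 h, 275 to 518 at 24 h, 1903 to 2406 in shoots at 7 h and 1618 to 1933 at 24 h. Tissue differences gave 1141 to 1661 at 7 h and 961 to 1263 at 24 h, and time differences 41 to 290 in roots and 176 to 411 in shoots. Shared calls ranged from 227 to 438 between tissues at 7 h, from 86 to 151 at 24 h and from 160 to 271 between times in roots.

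Median centring moved the median of all probe sets by 0.1425 for roots at 24 h of darkness, where 9015 were then higher and 4914 lower against 6331 and 5685, and by −0.169 between tissues in light. No called list or family changed sign.

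Replicate numbers are shared across groups but showed no clear pairing over all probe sets. Residuals of 45 pairs of groups correlated by −0.139 to 0.16 with a median of −0.0086, and 5 pairs lay over 0.1. The mean of the core low-oxygen list was higher in replicate 2 in every group but submerged shoots at 24 h. With the replicate block, submergence gave 1904, 735, 3092 and 2718 calls, and the other counts stayed within 1.5 times. Without light arrays submergence gave 2229, 890, 3351 and 2981.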

Other observations

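The families of gene symbols below, and the genes named from them, were chosen after the probe table or their values were seen, and the tests of these families were chosen in the same way. In dark roots at 24 h most measured genes of the TUB family of beta-tubulins and of the TBL family, for proteins that acetylate wall polymers, fell, and at 7 h most of the GSTU family, glutathione transferases of the tau class. Most genes of the ALDH family of aldehyde dehydrogenases, several of which act in amino acid breakdown, rose at 7 h. Dark shoots lowered the measured CRR genes, grouped here by symbol alone.

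In dark roots 8 of 9 XTH genes fell at both times, with means of −2.67 at 7 h (adjusted p = 2.1e-06, 0.05 with an estimated correlation) and −3.01 at 24 h (5.5e-06 and 0.052). Of 11 GSTU genes 9 fell and 1 rose at 7 h, with a mean of −1.59 (adjusted p = 0.0005, 0.082 with an estimated correlation), led by GSTU20 at −4.71. All 5 TUB genes fell at 24 h, with a mean of −1.80 (adjusted p = 0.0053, 0.2 with an estimated correlation), and TUB1 fell by 4.93. Of 22 TBL genes 14 fell and 2 rose at 24 h, with a mean of −0.82 (adjusted p = 0.0013, 0.052 with an estimated correlation). Of 8 ALDH genes 7 rose at 7 h, with a mean of 1.28 (adjusted p = 0.00068, 0.11 with an estimated correlation), among them ALDH7B4 by 2.7 and ALDH6B2, of valine breakdown, by 2.56. RNA polymerase II subunits of the NRPB family fell in 5 of 6 genes at 7 h, with a mean of −0.95 (adjusted p = 0.0077, 0.33 with an estimated correlation).

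In dark shoots all 5 CRR genes fell, with means of −2.15 at 7 h (adjusted p = 0.00099, 0.18 with an estimated correlation) and −2.17 at 24 h (0.0015 and 0.21), and CRR21 fell by 3.76 and 3.43. Of 7 CML genes 3 rose in submerged shoots at 7 h, with a mean of 1.16 (adjusted p = 0.0048, 0.2 with an estimated correlation), and 3 in submerged roots, with a mean of 0.71 (0.01 and 0.28).

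The 69 plastid-encoded genes were all lower in roots than in shoots in the light, by a mean of 3.93 (adjusted p = 7.7e-22, 0.49 with an estimated correlation). In submerged roots they had means of −0.47 at 7 h (adjusted p = 0.01, 0.82 with an estimated correlation) and 0.29 at 24 h (0.00027 and 0.92). Their medians on the arrays at 7 h were 5.99 and 6.82 in dark roots and 6.31 and 5.13 in submerged roots, so the replicates differed as much as the groups.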
